A study of Oryza sativa with 15 samples.

How the data were processed

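RNA of rice, cultivar Nipponbare, was measured on 1-colour Agilent arrays in 15 samples: egg cell, synergid cell, ovary soaked in mannitol for 8 h (5 ovaries), ovary without mannitol and whole plant, 3 replicates each. Per the labels, plants grew in pots under natural conditions, total RNA was taken with a PicoPure kit and its quality read on a Bioanalyzer, and labelled RNA was made with a linear amplification kit for low RNA input with a longer cDNA synthesis of 6 h. The number of cells pooled per sample, the storage time of the cells, the stage of the whole plants and whether the untreated ovaries were also kept for 8 h are not given in the sources used here. Per the file headers the spot intensity values are those of Agilent Feature Extraction 9.5.1.1 (9.5.3.1 for slide 2), with a 1-colour protocol, background subtraction, spatial detrending and multiplicative detrending within each array and no scaling between arrays. The raw spot and background intensities and the quality marks of each spot come from the same deposited files. The deposited series table by the authors holds linear signal values: each column's 75th percentile is near 10, its lowest value is 0.01, and its median ratio to the scaled processed intensity is 10.2 to 10.8, so it served as an alternative.

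The processed intensity was divided by the array's 75th percentile over gene spots and taken as log2. Spots marked as outliers were left out, and a probe without a value on an array was left out of fits with that array. Control spots were left out, as were artificial probes, 3.72% of probes, which leaves 41889 gene probes for 29689 loci, 7796 of them with more than 1 probe. Probes well above background on all 3 arrays of at least 1 group were kept, 36775 probes of 25628 genes, and the probe with the highest mean over 15 arrays stood for its gene. Where several probes of a gene passed, between 0.701 and 3.67% of such genes had probes that went opposite ways, and no gene named is among them. Values under a floor were set to it, and probes at the floor on every array of a comparison were not tested. The floor of a comparison is the highest, over its arrays, of each array's lowest scaled intensity among probes well above background, between -5.46 and -2.66 log2, and was settled after seeing the files. A fold against a group with all 3 arrays at the floor is written as at least that fold, and with 1 or 2 arrays at the floor the change is a low estimate. Gene spots well above background came to 66.2, 69.6, 75.9% in egg arrays 1 to 3, 54.6, 55.1, 52.8% in synergid arrays, 82.7, 86.6, 77.8% in soaked ovary, 82.3, 88.5, 80.8% in untreated ovary and 86.3, 87.6, 79.8% in whole plant arrays. The 75th percentile intensities in the same order were 448, 628, 162, then 70, 46.2, 47.4, then 693, 884, 805, then 940, 1243, 1215, then 649, 620, 523. The median SD between replicates was 0.164 log2 in egg, 0.192 in synergid, 0.381 in soaked ovary, 0.156 in untreated ovary and 0.413 in whole plant arrays.

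Each of 7 comparisons was a fit of its 6 arrays in limma 3.58.1 (lmFit and eBayes), and a gene passed with a Benjamini-Hochberg adjusted p under 0.05 over all probes tested, 2-sided. The eBayes prior was taken from probes above the floor on at least 2 arrays of each group. Comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, except the floor, the source of the prior and the alternatives named in the text as chosen after seeing the data. Enriched sets hold genes that passed with the cell at least 2-fold higher in each fit: egg over the other 4 groups, synergid over the other 4, or each cell over the 3 tissues. Lists were made from gene descriptions and names, and 25 were written: photosynthesis, floral organ MADS-box, egg cell secreted EC1-like, small secreted cysteine-rich peptides, pollen allergens, seed storage proteins, cytosolic ribosomal proteins, translation factors, core histones, small RNA and chromatin silencing, DNA replication and cell cycle, F-box and SKP1 proteins, proteasome, secretory pathway, cell wall, mitochondrial respiration, heat shock proteins, osmotic stress and abscisic acid, aquaporins, low oxygen and fermentation, jasmonate, pathogenesis-related and WRKY, detoxification and redox, auxin response, AP2/ERF, WOX and RWP-RK regulators. Loci that the patterns caught by mistake were removed on their descriptions, before any expression value was seen: 64 for seed storage, 46 for photosynthesis, 39 for cysteine-rich peptides, 36 for pathogenesis-related, 34 for pollen allergens, 7 for low oxygen and 5 for AP2/ERF. Lists were tested with limma's camera with a preset correlation of 0.01 and adjusted over the 24 lists of a comparison with at least 5 measured genes. With the correlation between genes estimated instead, none of the 99 list calls held, and 18 of 168 lists had an unadjusted p under 0.05. Members in the enriched sets were tested by Fisher's exact test, 1-sided, against genes tested in every fit of the set.

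Genes named in the text passed with no overlap between groups, were well above background on all 3 arrays of the brighter group and have a stated function. They were drawn from the 10 largest changes each way for egg against synergid and soaked against untreated ovary, the 5 largest each way in other comparisons, the 10 with the largest smallest fold in each set, and up to 2 members each way per list. The files put egg arrays 1 and 2 on slide 1, egg array 3 and the synergid arrays on slide 2, and the tissues of replicate 1, 2 and 3 on slides 3, 4 and 5, so tissue replicates of a number are paired by slide. Residuals of same-number arrays correlated across probes at 0.197, 0.16, 0.245 for soaked and untreated ovary and at 0.245, 0.129, 0.292 for untreated ovary and whole plant, above every other pairing, but at 0.067, -0.073, 0.016 for egg and synergid cells. Replicate number and slide were each tried as a block. For cell and tissue comparisons slide was a random block, with a consensus correlation of 0.161. Cells and tissues shared no slide and no scan day, so that block cannot separate their difference from either.

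The procedure was tested on simulated data with the spread of these arrays. For egg against synergid it recovered 56 of 100 genes changed 2-fold and 87 of 100 changed 4-fold, and called 7 of 19427 unchanged genes. For soaked against untreated ovary, whose spread is wider, it recovered 0 and 38 of 100 and called 1 of 24557. A proteasome list shifted 2-fold was called in each and the other 23 lists were not, and 86 of 200 genes raised 4-fold in egg cells entered the egg-enriched set. Noise was drawn for each probe independently, so the list result does not cover lists whose genes vary together. Far fewer genes were changed than passed in the data, so the shares recovered need not hold for the real fits. Alternatives were normexp background correction with an offset of 50, quantile normalization, the 75th percentile over probes detected on all arrays, the series table, no filter, only probes detected on all arrays of both groups, a single fit of 15 arrays, an intensity trend, the mean of a gene's probes, fold minimums, the blocks, each replicate left out, fry and the estimated correlation. Fits ran in R 4.3.3 with data.table (version 1.17.8), and files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No locus of the arrays was found in the reference table at hand, so gene names are those of the array annotation.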

Results

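The arrays compare RNA of rice cells and tissues in 5 groups of 3 arrays each: egg cells, synergid cells, ovaries kept for 8 h in mannitol, ovaries without mannitol and whole plants. The egg cell is the female gamete, and the synergid cells lie beside it in the embryo sac and draw in the pollen tube. Per the labels the soaked ovaries, 5 to a sample, test what storage of isolated cells in mannitol does to their RNA. The synergid arrays were the dimmest, with 52.8 to 55.1% of gene spots well above background and a 75th percentile signal of 46.2 to 70. Egg arrays had 66.2 to 75.9% and 162 to 628, and the 9 tissue arrays 77.8 to 88.5% and 523 to 1243. Across probes kept, which are not independent replicates, log2 values had Pearson correlations of 0.805 to 0.827 between egg and synergid arrays. The correlation was 0.477 to 0.557 between egg and soaked ovary arrays, 0.742 to 0.756 between the 2 kinds of ovary, and at least 0.877 between arrays of any single group. Soaked ovary array 1 and whole plant array 1, both on slide 3, stood apart from their replicates: 0.924 and 0.93 against 0.99 between the other soaked arrays, and 0.904 and 0.877 against 0.98 between the other plant arrays. Egg arrays 1 and 2 shared slide 1, egg array 3 and the synergid arrays shared slide 2, and slides 3, 4 and 5 each held a sample of all 3 tissues. Values below are log2 of signal over the array's 75th percentile, given as mean ± SD over 3 arrays of a group. Changes are log2 fold changes unless a fold is named, and each gene named in a comparison passed with no overlap between the 3 arrays of each group. Counts of list members adjusted over the list alone stand in parentheses where they differ from the counts over all genes, and elsewhere the counts adjusted over the list alone were the same. With 3 arrays against 3, chance alone parts the groups without overlap for 10% of genes. The series calls the replicates biological but nothing says that they came from separate plants, so the p-values measure the spread between these samples.

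The series title names the profiles of egg and synergid cells, and the comparison of the 2 cells asks which genes set them apart. A gene of an RWP-RK domain protein, of a family that includes regulators of the egg cell, stood at 7.29 ± 0.13 in the egg cell against 2.09 ± 0.43 in the synergid cell (Os06g0228900, change 5.20, adjusted p = 6.37e-07). An ECA1 protein gene, of a family that includes secreted egg cell proteins, was at 7.79 ± 0.71 against 3.95 ± 0.16 (Os03g0296600, 3.84, adjusted p = 1.63e-05). The egg cell also had more RNA of a ubiquitin domain protein (5.63 ± 0.26 against -0.27 ± 0.30, Os07g0574500, 5.90), an HSP70 chaperone (Os11g0187600, 5.75) and an Argonaute protein of small-RNA silencing (Os03g0682200, 5.38). In the other direction a beta-1,3-glucanase, an enzyme that cuts callose, was at -2.35 ± 0.53 in the egg cell and 7.54 ± 0.16 in the synergid cell (Os09g0533200, -9.89, adjusted p = 9.46e-08). Synergid cells were also higher for an allergen V5 family protein (Os04g0289500, -9.60), the lipid-binding transfer protein nsLTP2 (Os03g0111300, -9.36), a chalcone synthase family protein (Os11g0529500, -9.21) and a family 28 glycoside hydrolase (Os03g0124900, -9.23).

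**Figure D1:**
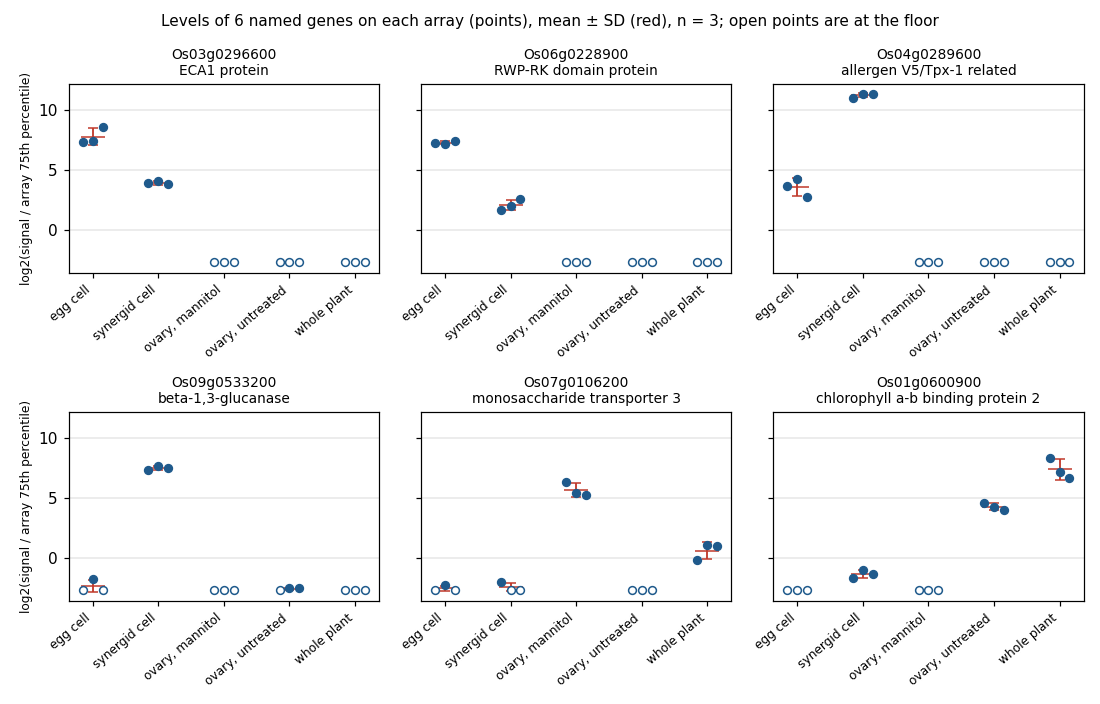
Log2 of signal over the array's 75th percentile (vertical axis) for 6 named genes in the 5 groups (horizontal axis), 1 point per array, open where it lies at a floor shared by the 15 arrays, with red bars for mean ± SD over 3 arrays. The beta-1,3-glucanase stands at 7.54 ± 0.16 in the synergid cell and -2.35 ± 0.53 in the egg cell.

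Of 19669 genes tested between egg and synergid cells, 11833 passed in limma, 6469 higher in the egg cell and 5364 higher in the synergid cell. Between egg array 3 and the synergid arrays within slide 2, 4332 genes were at least 2-fold higher in the egg cell and 3230 in the synergid cell. Genes called without egg array 3 and 1 synergid array had the same sign between the arrays left out in 92.42 to 95.73% of cases. A slide block leaves the change between these cells to egg array 3 alone, assumed to vary like the other arrays, so its p-values for lists here rest on a single egg sample. Protein synthesis stood out: of 243 cytosolic ribosomal protein genes, 217 were higher in the egg cell and 5 in the synergid cell (220 and 5 adjusted over the list alone), with a median of 1.56 and camera adjusted p = 1.88e-22. Examples are L30 (Os01g0812800, 3.05) and, against the list, L12 (Os05g0568300, -1.84). Translation factors had 34 and 5 of 53 higher in the egg and synergid cell (median 0.78, camera adjusted p = 0.000435), among them elongation factor EF1b2 (Os03g0406200, 2.37). For DNA replication and cell cycle genes the counts were 15 and 3 of 25, median 0.81, camera adjusted p = 0.0172, but an adjusted p of 0.0921 after normexp correction and of 0.0652 with a slide block. DNA polymerase alpha (Os01g0868300, 2.61) was higher in the egg cell and replication protein RPA1 (Os03g0214100, -3.71) in the synergid cell. F-box and SKP1 proteins numbered 130 and 47 of 286 (median 0.34, camera adjusted p = 0.0113, 0.286 after normexp). Proteasome genes numbered 25 and 4 of 55 (24 and 2 adjusted over the list alone) (median 0.38, camera adjusted p = 0.0172), with adjusted p = 0.162 after quantile normalization and 0.214 with a slide block. None of these 5 lists passed with the correlation estimated: adjusted p = 0.201, 0.201, 0.201, 0.201 and 0.501 with an estimated correlation, in that order. Within slide 2 their medians were, in the order given, 1.57, 0.72, 0.87, 0.40 and 0.30.

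Lists higher in the synergid cell included cell wall genes, of which 115 were measured: 15 were higher in the egg cell and 62 in the synergid cell (15 and 64 adjusted over the list alone), median -0.76, camera adjusted p = 2.6e-05. A xyloglucan fucosyltransferase (Os08g0334900, at least 158-fold higher in the synergid cell) and a pectin methylesterase inhibitor (Os04g0587200, -6.20) went with the list, and a pectinesterase (Os01g0743200, 3.61) went against it. Counts below give genes higher in the egg cell and then in the synergid cell. Small secreted cysteine-rich peptides had 5 and 24 of 43 (median -0.93, camera adjusted p = 0.000435), and all 5 aquaporins measured were higher in the synergid cell (median -1.91, camera adjusted p = 0.00267), such as Os02g0666200 (-5.01). Floral organ MADS-box genes had 2 and 9 of 15 (median -1.04, camera adjusted p = 0.0102, 0.38 after normexp). MADS15 (Os07g0108900, 3.82) was higher in the egg cell and a PISTILLATA-like gene (Os01g0883100, -3.49) in the synergid cell. Osmotic stress and abscisic acid genes had 9 and 30 of 63 (median -0.65, camera adjusted p = 0.00491, 0.077 after normexp), among them EFA27 (Os02g0734600, -5.45). Secretory pathway genes had 11 and 26 of 56 (median -0.35, camera adjusted p = 0.0113), but after normexp their median of -0.03 lay above that of all genes with adjusted p = 0.0395. Pollen allergens had 0 and 6 of 10 (median -1.01, camera adjusted p = 0.0118). Jasmonate genes had 6 and 15 of 28 (median -0.65, camera adjusted p = 0.0319, 0.0652 with a slide block), with a lipoxygenase at -4.32 (Os03g0700700). None of these 8 lists passed with the correlation estimated: adjusted p = 0.236 for cell wall, 0.245 for cysteine-rich peptides and for aquaporins, 0.429 for MADS-box genes, 0.201 for osmotic stress and jasmonate, and 0.284 for the secretory pathway and pollen allergens, with an estimated correlation. Medians within slide 2 were, in the order given, -0.57, -1.01, -1.46, -1.04, -0.46, -0.30, -0.59 and -0.60.

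The last 3 lists called between egg and synergid cells were higher in the synergid cell and had adjusted p between 0.0172 and 0.0437. Pathogenesis-related and WRKY genes had 13 and 36 of 97 (median -0.26, camera adjusted p = 0.0172), and photosynthesis genes 7 and 20 of 50 (median -0.34, camera adjusted p = 0.0302), and both calls held after quantile normalization (0.0336 and 0.0364). Auxin response genes had 7 and 15 of 39 (median -0.18, camera adjusted p = 0.0437), but adjusted p = 0.225 after quantile normalization and 0.0511 with the 75th percentile taken over probes detected on all arrays. After normexp pathogenesis-related (0.00177) and auxin response genes (0.00446) passed and photosynthesis did not (0.0705). With a slide block the adjusted p of the 3 lists was 0.104, 0.214 and 0.268, and adjusted p = 0.429, 0.526 and 0.429 with an estimated correlation. Within slide 2 their medians were -0.09, -0.32 and -0.16. The other 8 lists tested did not pass: regulators of the AP2/ERF, WOX and RWP-RK families had 14 and 27 of 71 (camera adjusted p = 0.0577), silencing genes 10 and 3 of 30 (0.114) and core histones 11 and 18 of 46 (0.253). Heat shock proteins had 37 and 49 of 138 (0.308), detoxification 42 and 39 of 153 (41 and 39 adjusted over the list alone) (0.639), low oxygen 18 and 13 of 38 (0.93), respiration 11 and 8 of 49 (9 and 7 adjusted over the list alone) (0.974) and seed storage proteins 1 and 1 of 5 (0.962). Core histones passed as lower in the egg cell with a slide block (0.04) and after quantile normalization (0.0364), but as higher after normexp (0.0333, median -0.17 above that of all genes). AP2/ERF regulators passed as lower after quantile normalization (0.0364), and silencing (0.0113) and respiration (3.71e-08) as higher after normexp. Medians and means differ in sign for heat shock (0.01 and -0.13, the test lower in the egg cell), seed storage (0.11 and -0.26, lower) and low oxygen (0.27 and -0.14, higher). The list of EC1-like secreted egg cell proteins held only the ECA1 gene and was not tested.

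The split between egg and synergid cells depends on how dim spots are handled. After normexp correction, which moved the median of all genes by -1.03, 20220 genes passed, 4733 higher in the egg cell and 15487 in the synergid cell. With each array floored at its own lowest detected signal, a choice made after seeing the data, the counts were 6054 and 10506. Quantile normalization moved the median by 0.27. With a fold minimum of 2 the count was 7557, 3989 and 3568.

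Soaked against untreated ovaries asks how tissue RNA differs after 8 h in mannitol. Whether the untreated ovaries were also kept for 8 h is not given, so mannitol and time out of the plant cannot be told apart here. A monosaccharide transporter gene stood at 5.67 ± 0.59 in the soaked ovary and -5.44 ± 0.03 in the untreated ovary, where 2 of 3 arrays lay at the floor (Os07g0106200, 11.11, adjusted p = 6.94e-06). Among the largest rises were also peroxidase P7 (Os06g0547400, 10.84), a jacalin-related lectin (Os01g0348900, 10.39), the probenazole-inducible gene PBZ1 (Os12g0555300, 10.13) and a class III chitinase (Os11g0702100, 9.62). A Bet v I family gene rose as well (Os12g0555000, at least 1170-fold, detected on 0 of the 3 untreated arrays). Chlorophyll a/b binding protein 2 fell from 4.29 ± 0.28 to -3.03 ± 0.20 (Os01g0600900, -7.31, adjusted p = 7.69e-06). A CBF-like factor (Os06g0127100, -6.24), a thiazole synthesis enzyme (Os07g0529600, -5.48) and a pectinesterase (Os01g0743200, -5.44) also fell.

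**Figure D2:**
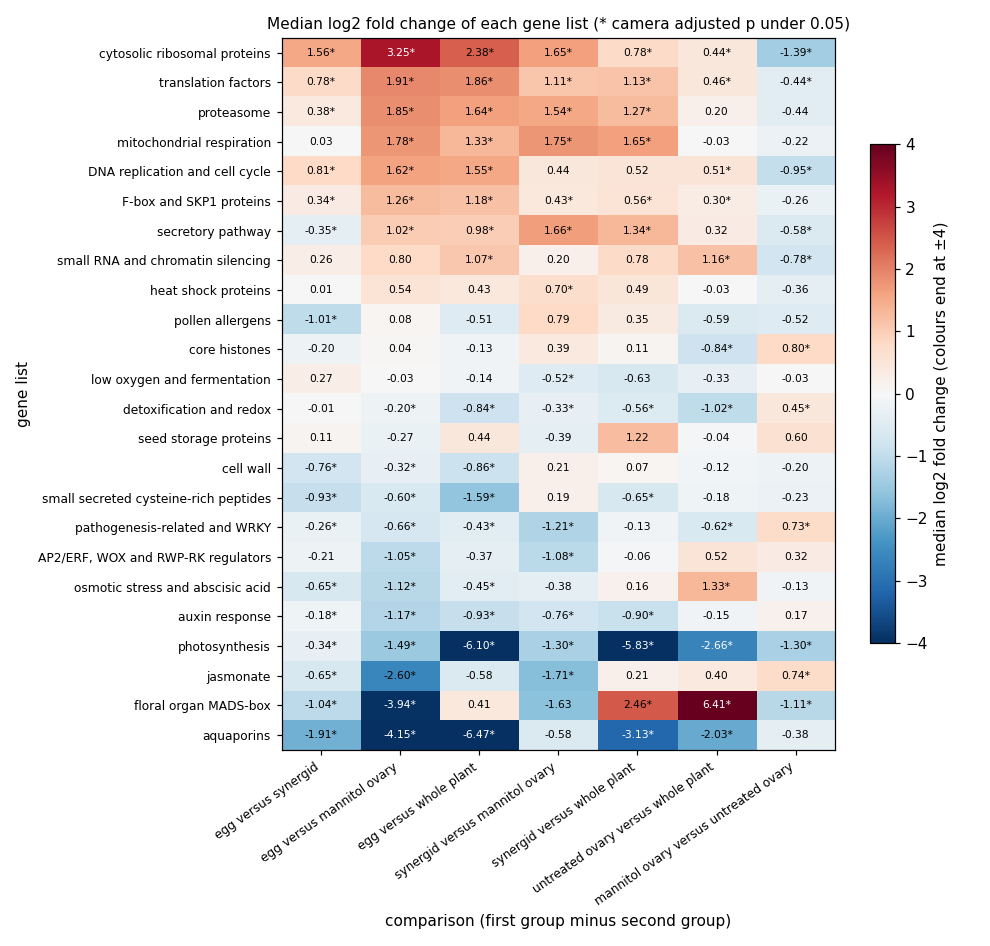
Median log2 fold change (colour) of 24 gene lists (vertical axis) in the 7 comparisons (horizontal axis), with a star where camera's adjusted p is under 0.05. Ribosomal proteins have a median of 1.56 in egg against synergid cells and -1.39 in soaked against untreated ovaries, and both calls held after normexp, after quantile normalization and with the percentile over detected probes but not with the correlation estimated (adjusted p = 0.201 and 0.133 with an estimated correlation).

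Of 24777 genes, 13427 passed, 6080 higher in the soaked ovary and 7347 lower, and 7623 and 8868 without soaked array 1. At least 2-fold within a slide were 5067 and 5993 genes on slide 3, 5655 and 6651 on slide 4 and 6082 and 6628 on slide 5, higher and lower in that order. Lists passed in 11 of 24 cases. Ribosomal proteins fell together: of 246, 5 rose and 208 fell (5 and 211 adjusted over the list alone), median -1.39, camera adjusted p = 9.42e-20, and -1.43, -1.46 and -1.32 within slides 3, 4 and 5. L6 fell (Os03g0356300, -3.56), while S12/S23 (Os07g0137900, 1.52) and a gene of the list that encodes S6 kinase rather than a ribosomal protein (Os03g0334000, at least 4.45-fold, but 0.01 with a single floor over all 15 arrays) rose. Photosynthesis genes had 1 and 43 of 71 that rose and fell, median -1.30 (-1.94, -1.06 and -1.08 by slide) and camera adjusted p = 1.29e-06, with PsbS at -5.01 (Os01g0869800). Pathogenesis-related and WRKY genes had 66 and 18 of 147, median 0.73 (0.75, 0.62 and 0.69 by slide), camera adjusted p = 0.000176. Jasmonate genes had 18 and 6 of 37 (18 and 7 adjusted over the list alone), median 0.74 (0.85, 0.92 and 1.12), camera adjusted p = 0.0081, among them a ZIM domain gene (Os04g0395800, at least 85-fold). Detoxification and redox genes had 80 and 43 of 229, median 0.45 (0.35 to 0.38 within slides), camera adjusted p = 0.0141. None of the 5 passed with the correlation estimated: adjusted p = 0.133 for ribosomal and for pathogenesis-related genes, 0.47 for photosynthesis and jasmonate, and 0.164 for detoxification, with an estimated correlation.

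Another 6 lists passed, counted as genes that rose and fell in the soaked ovary. DNA replication and cell cycle had 2 and 18 of 32 (3 and 21 adjusted over the list alone), median -0.95 (-1.42 to -0.72 within slides), camera adjusted p = 0.00225, with the cell cycle subunit CKS1 at -2.98 (Os03g0146300). Small RNA and chromatin silencing had 1 and 15 of 33, median -0.78 (-0.68 to -0.57), camera adjusted p = 0.0141, among them Argonaute 4 (Os01g0275600, -3.20) and an SNF2 protein (Os09g0442700, -4.52). MADS-box genes had 0 and 8 of 15, median -1.11 (-1.23 to -0.80), camera adjusted p = 0.0403, with AGAMOUS at -2.56 (Os01g0886200). Translation factors had 7 and 21 of 54, median -0.44 (-0.62 to -0.32), camera adjusted p = 0.0403, and the secretory pathway 6 and 20 of 57 (6 and 19 adjusted over the list alone), median -0.58 (-0.77 to -0.17), camera adjusted p = 0.0452. Core histones passed as higher with 11 and 3 of 46 (10 and 3 adjusted over the list alone), median 0.80, camera adjusted p = 0.0234, 0.0865 after normexp, for example an H4 (Os05g0466600, 2.97), but their medians within slides 3, 4 and 5 were -0.67, 1.75 and 1.25. For these 6 lists the estimate gave adjusted p = 0.164 for replication and silencing, 0.47 for translation factors, 0.672 for MADS-box genes, and 0.702 for secretion and histones, with an estimated correlation. Proteasome genes, 5 and 14 of 54 (4 and 11 adjusted over the list alone), did not pass (camera adjusted p = 0.134), but did as lower after quantile normalization (0.0322) and normexp (0.00362). Osmotic stress and abscisic acid genes did not pass either (median -0.13, camera adjusted p = 0.574). The same held for aquaporins (-0.38, 0.544), low oxygen (-0.03, 0.444) and heat shock proteins (-0.36, 0.128). Normexp moved the median of all genes by 0.32, with 5699 and 4755 genes higher and lower.

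The soaked ovary is also the tissue held in the solution in which, per the labels, isolated cells were kept, so each cell was compared with it. In the egg cell the ECA1 gene was at 7.79 ± 0.71, at least 3370-fold above the soaked ovary, where 1 of 3 arrays detected it (Os03g0296600, adjusted p = 1.66e-06). The RWP-RK gene (Os06g0228900, at least 2380-fold, 1 of 3 arrays) and an LRR protein gene (Os05g0491400, at least 951-fold, 0 of 3) were higher in the egg cell too. Lower in the egg cell were phenylalanine ammonia-lyases of phenylpropanoid synthesis (Os02g0626100, -10.86, and Os02g0626400, -10.11) and a homeodomain leucine zipper gene (Os03g0198600, -10.41). In the synergid cell the allergen V5 gene Os04g0289600 was at least 15500-fold higher than in the soaked ovary (adjusted p = 1.01e-07), at 11.26 ± 0.18. A family 20 glycoside hydrolase (Os05g0415700, at least 3430-fold) and nsLTP2 (Os03g0111300, 10.25) were likewise higher. The monosaccharide transporter (Os07g0106200, -8.12) and peroxidase P7 (Os06g0547400, -7.96) were lower in the synergid cell than in the soaked ovary. Both had risen in the soaked ovary against the untreated one (11.11 and 10.84), so these values do not mark the synergid cell as low against ovary without mannitol.

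Of 24198 genes tested between egg cell and soaked ovary, 14987 passed, 8382 higher in the egg cell and 6605 in the ovary, and 18 lists passed. Which side held more genes depends on egg array 3 and the scaling: the counts were 8466 and 8766 without that array and 7468 and 7495 with the 75th percentile over probes detected on all arrays, which moved the median of all genes by -0.16. Among probes detected on all 6 arrays the counts were 7403 and 4085, and after normexp 6918 and 4606. Ribosomal proteins numbered 228 and 2 of 247 (229 and 2 adjusted over the list alone) higher in the egg cell and in the ovary, median 3.25, camera adjusted p = 9.14e-27, with P0 (Os11g0135400, 6.94) and L30 (Os01g0812800, 6.37). Proteasome genes had 48 and 0 of 55, median 1.85, camera adjusted p = 3.61e-07, translation factors 39 and 5 of 53, median 1.91, camera adjusted p = 1.06e-05, and respiration 36 and 5 of 49, median 1.78, camera adjusted p = 0.000266. Higher in the soaked ovary were photosynthesis, 3 and 45 of 68 (3 and 46 adjusted over the list alone), median -1.49, camera adjusted p = 4.58e-07, and jasmonate genes, 5 and 25 of 36 (5 and 26 adjusted over the list alone), median -2.60, camera adjusted p = 2.57e-05, with a ZIM domain gene (Os03g0180900, -7.64). Pathogenesis-related and WRKY genes had 11 and 61 of 141, median -0.66, camera adjusted p = 2.11e-05. These 7 lists gave adjusted p = 0.165, 0.349, 0.185, 0.349, 0.339, 0.339 and 0.339 with an estimated correlation, in that order. In soaked against untreated ovary their medians were -1.39, -0.44, -0.44, -0.22, -1.30, 0.74 and 0.73, in the same order. The change of the soaked ovary thus enters the list values here, which need not hold against ovary without mannitol. Cell wall genes, 25 and 50 of 141, median -0.32, camera adjusted p = 0.0203, narrowly missed the threshold after normexp (0.0515, and adjusted p = 0.453 with an estimated correlation). Cell and tissue arrays shared no slide, so no value within a slide can be had for them.

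Between synergid cell and soaked ovary 12557 of 20037 genes passed, 7212 higher in the synergid cell and 5345 in the ovary. The counts were 16886 and 3775 after normexp, which moved the median of all genes by 1.06, and 13518 and 5488 with each array's own floor. Among probes detected on all 6 arrays they were 6865 and 3034. Quantile normalization moved the median by -0.25 and the percentile over detected probes by -0.13. Of the 14 lists that passed, ribosomal proteins had 214 and 6 of 239 (216 and 8 adjusted over the list alone) higher in the synergid cell and in the ovary, median 1.65, camera adjusted p = 1.32e-17. Jasmonate genes had 2 and 25 of 32 (2 and 26 adjusted over the list alone), median -1.71, camera adjusted p = 1.56e-05. Secretory pathway genes had 42 and 6 of 54, median 1.66, camera adjusted p = 0.000214, with coatomer epsilon (Os04g0644700, at least 44.3-fold), but 0.45 after normexp. Respiration had 37 and 8 of 49 (38 and 8 adjusted over the list alone), median 1.75, camera adjusted p = 0.000228, 0.454 after normexp, with a ubiquinol-cytochrome c reductase subunit (Os02g0541700, 5.32). The proteasome had 45 and 1 of 54 (46 and 1 adjusted over the list alone), median 1.54, camera adjusted p = 1.16e-05, 0.618 after normexp. Pathogenesis-related and WRKY genes, 14 and 59 of 112, median -1.21, camera adjusted p = 3.13e-05, had a median of 1.19 after normexp, still below that of all genes (0.00385). The 6 lists gave adjusted p = 0.316, 0.316, 0.367, 0.357, 0.447 and 0.166 with an estimated correlation, in that order. In soaked against untreated ovary their medians were -1.39, 0.74, -0.58, -0.22, -0.44 and 0.73, in the same order. Part of these differences may thus be the change of the soaked ovary, and they need not hold against ovary without mannitol.

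Against whole plants, which hold green tissue, the cells held less RNA of photosynthesis genes. The small subunit of Rubisco was at -3.70 ± 0.39 in the egg cell and 8.13 ± 0.28 in the plant (Os12g0274700, -11.84, adjusted p = 1.62e-06), and at least 1770-fold lower in the synergid cell. Chlorophyll a/b binding protein 1 was lower in the egg cell (Os09g0346500, -11.48), and so was metallothionein type 3 in the egg (Os01g0200700, -11.30) and synergid cell (-10.20). Higher in the egg cell were the ECA1 gene (Os03g0296600, at least 3370-fold, detected on 0 of 3 plant arrays), the RWP-RK gene (Os06g0228900, at least 2380-fold, 2 of 3) and an Argonaute 4 gene (Os07g0471300, 7.34). Higher in the synergid cell were allergen V5 (Os04g0289600, at least 15500-fold), the beta-1,3-glucanase (Os09g0533200, at least 1170-fold, detected on 3 of 3 plant arrays but at the floor of the comparison) and the chalcone synthase family gene (Os11g0529500, 10.04).

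Egg cell and whole plant differed in 14334 of 24616 genes, 8118 higher in the egg cell and 6216 in the plant, but 6150 and 8401 with the percentile taken over detected probes, which moved the median of all genes by -0.37, and 8001 and 8432 without egg array 3. Among probes detected on all 6 arrays the counts were 7206 and 3263. After normexp, which moved the median by -0.37, 6851 genes passed, 3655 and 3196. Quantile normalization moved the median by 0.16. Photosynthesis genes had 2 and 62 of 71 higher in the egg cell and in the plant, median -6.10, camera adjusted p = 2.09e-19. Ribosomal proteins had 217 and 6 of 246 (220 and 6 adjusted over the list alone), median 2.38, camera adjusted p = 5.34e-19, the proteasome 50 and 2 of 55, median 1.64, camera adjusted p = 5.07e-09, and F-box and SKP1 proteins 189 and 35 of 331 (191 and 36 adjusted over the list alone), median 1.18, camera adjusted p = 2.03e-06, with an SKP1 (Os07g0625400, 7.26). Aquaporins had 0 and 6 of 9, median -6.47, camera adjusted p = 0.000636, with a delta-type tonoplast protein (Os06g0336200, -9.01). Cysteine-rich peptides had 6 and 32 of 56 (6 and 33 adjusted over the list alone), median -1.59, camera adjusted p = 1.51e-05. Those 6 of the 16 lists that passed gave adjusted p = 0.31 for each with an estimated correlation.

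Synergid cell and whole plant differed in 11687 of 20902 genes, 6908 higher in the synergid cell and 4779 in the plant. With the percentile over detected probes, which moved the median of all genes by -0.29, the counts were 5214 and 6931, with each array's own floor 11959 and 5027, and among probes detected on all 6 arrays 6539 and 2167. After normexp, which moved the median by 0.63, 3317 genes passed, 2003 and 1314. Quantile normalization moved the median by -0.15. Photosynthesis genes had 1 and 58 of 67 (1 and 59 adjusted over the list alone) higher in the synergid cell and in the plant, median -5.83, camera adjusted p = 4.11e-21. MADS-box genes had 11 and 0 of 15, median 2.46, camera adjusted p = 0.000806, with a PISTILLATA-like gene (Os01g0883100, 5.95). Proteasome genes had 45 and 1 of 54 (45 and 2 adjusted over the list alone), median 1.27, camera adjusted p = 7.47e-07, and the secretory pathway 41 and 7 of 58 (44 and 7 adjusted over the list alone), median 1.34, camera adjusted p = 0.000103. Ribosomal proteins had 126 and 12 of 241, median 0.78, camera adjusted p = 9.57e-05, and 0.688 after normexp. Those 5 of 12 lists gave adjusted p = 0.399, 0.481, 0.481, 0.481 and 0.649 with an estimated correlation, in that order.

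Untreated ovary against whole plant gives the background of tissue differences. The RAP2.2 gene, of an ethylene response factor family, was at least 1460-fold higher in the ovary (Os07g0674800, adjusted p = 3.25e-06, detected on 1 of 3 plant arrays). MADS-box genes of floral organs (Os08g0531700, 9.42, and Os05g0203800, 9.25), AGAMOUS (Os01g0886200, 6.41) and an Argonaute gene (Os07g0188000, 8.84) were higher in the ovary as well. Lower in the ovary were the photosystem II 10 kDa protein (-4.89 ± 0.68 against 6.01 ± 1.22, Os07g0147500, -10.90), a proline-rich protein (Os04g0644400, at least 804-fold) and a glutathione transferase (Os10g0530400, -8.90).

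Of 25072 genes, 11797 passed, 5986 higher in the untreated ovary and 5811 in the whole plant, and 7611 and 7900 without plant array 1. At least 2-fold within slides 3, 4 and 5 were 5088 and 5453, 5103 and 6477, and 5303 and 5958 genes. The split was 1787 and 3303 after normexp, which moved the median of all genes by -0.58, and 4765 and 7010 with the percentile over detected probes, which moved it by -0.19. Quantile normalization moved it by 0.18, and with a slide block the split was 5744 and 6046. MADS-box genes had 13 and 0 of 15 (13 and 1 adjusted over the list alone) higher in the ovary and in the plant, median 6.41 (6.80, 5.54 and 6.44 within slides 3, 4 and 5), camera adjusted p = 6.21e-09. Photosynthesis genes had 1 and 54 of 71 (1 and 56 adjusted over the list alone), median -2.66 (-3.22, -2.62 and -2.28), camera adjusted p = 5.96e-13. Silencing genes had 20 and 0 of 32 (22 and 0 adjusted over the list alone), median 1.16 (1.30, 1.09 and 1.39), camera adjusted p = 4.04e-07, with Argonaute 4 (Os07g0471300, 4.31). Detoxification genes had 16 and 120 of 239 (16 and 122 adjusted over the list alone), median -1.02 (-0.88, -1.12 and -0.91), camera adjusted p = 1.06e-07. Osmotic stress and abscisic acid genes had 37 and 13 of 77, median 1.33 (0.83, 1.41 and 0.89), camera adjusted p = 0.0113, with an LEA protein (Os01g0705200, 8.63). Those 5 of 12 lists gave adjusted p = 0.305, 0.408, 0.305, 0.305 and 0.305 with an estimated correlation, in that order. Regulators of the AP2/ERF, WOX and RWP-RK families, 32 and 20 of 89 (33 and 21 adjusted over the list alone), did not pass (camera adjusted p = 0.052), but did with a slide block (0.0388) and with the percentile over detected probes (0.0344).

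Genes higher in a cell than in every other group, by at least 2-fold in each fit, make up the enriched sets. The egg-enriched set held 2237 of 19349 genes, 28 of them detected on no other array. With the smallest of their 4 folds, it includes a 3'-5' exonuclease domain gene (Os01g0299700, 60.2-fold), the ubiquitin domain gene (Os07g0574500, 59.5-fold), the Argonaute gene (Os03g0682200, 41.6-fold) and the RWP-RK gene (Os06g0228900, 36.7-fold). The synergid-enriched set held 1403 of 17550 genes, 15 of them detected on no other array, led by the beta-1,3-glucanase (Os09g0533200, 950-fold), allergen V5 (Os04g0289500, 775-fold), nsLTP2 (Os03g0111300, 656-fold) and the chalcone synthase family gene (Os11g0529500, 593-fold). Each cell exceeded all 3 tissues for 1668 of 18008 genes, 12 of which no tissue array detected. Calls of the 2 cells over the tissues, 4520 and 3243 genes, would share 814 if independent, and 20 simulated data sets without group differences gave 0 genes in each of the 3 sets. The value under independence leaves out the tissue arrays that serve both cells and the simulation leaves out all group differences, so an excess over either is no measure of a shared effect. The set of both cells includes the LRR gene (Os05g0491400, at least 324-fold), allergen V5 (Os04g0289600, at least 179-fold), the ECA1 gene (Os03g0296600, at least 97.7-fold) and a histone H2A (Os03g0721900, 92.7-fold). It can share genes with the other sets: Os04g0289600 is also synergid-enriched (209-fold).

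Fisher's exact test takes genes as independent, but members of a list can vary together. Among ribosomal protein genes the estimated correlation was 0.197 in egg against synergid cells, so the Fisher p-values overstate the evidence. By Fisher's exact test, 1-sided, ribosomal proteins were the list most common in the egg-enriched set (173 of 242 against 28 by chance, adjusted p = 6.72e-106). F-box and SKP1 proteins (68 of 285 against 33 by chance, adjusted p = 4.24e-08), DNA replication and cell cycle (10 of 25 against 2.89 by chance, adjusted p = 0.00211) and translation factors (14 of 52 against 6.01 by chance, adjusted p = 0.011) followed. In the set of both cells they were respiration (27 of 49 against 4.54 by chance, adjusted p = 1.57e-14), F-box and SKP1 proteins (63 of 245 against 22.7 by chance, adjusted p = 4.11e-13), the proteasome (23 of 53 against 4.91 by chance, adjusted p = 4.58e-10), ribosomal proteins (42 of 238 against 22 by chance, adjusted p = 0.000196), translation factors (13 of 52 against 4.82 by chance, adjusted p = 0.00329) and the secretory pathway (13 of 54 against 5 by chance, adjusted p = 0.00402). No list passed for the synergid-enriched set (3 of 23 had an unadjusted p under 0.05), the nearest being cell wall genes (17 of 103 against 8.23 by chance, adjusted p = 0.0664) and pollen allergens (4 of 10 against 0.799 by chance, adjusted p = 0.0664). The sets, which can share genes, were also looked up in the comparison of ovaries, without a test between sets. Of 2153 egg-enriched genes tested in the ovary comparison 60.33% were lower in the soaked ovary and 6.131% higher, against 29.65% and 24.54% of all genes. Among genes of both cells the shares were 41.24% and 6.528%, and among synergid-enriched genes 17.33% and 18.15%. After normexp the egg-enriched set fell to 1574 genes, the synergid-enriched set to 414 genes and the set of both cells to 473, which also fell to 1023 with the percentile over detected probes. With each array's own floor the synergid-enriched set held 2538 genes.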

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

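The settings chosen after seeing the data are the single floor over 15 arrays, each array's own floor, the prior from all tested probes, egg replicate 3 alone and the list test with a replicate block. Synergid arrays lay closest to background, so the floor was highest in the comparisons with synergid cells, where 19669 to 20902 genes could be tested, against at least 24198 in the others. After normexp correction 20220 genes passed between egg and synergid cells and 20661 between synergid cells and soaked ovary, against 6851 for egg and 3317 for synergid cells against whole plants and 5090 for untreated ovary against whole plants. Its offset of 50 compares with 75th percentile signals of 70, 46.2, 47.4 on the synergid arrays, so by construction it lifts most of their values toward a common level, and any further cause was not tested. The sets fell to 1574 egg-enriched genes, 414 synergid-enriched genes and 473 of both cells, 57.4, 29.5 and 28.4% of the main sets being shared. With the percentile over detected probes the set of both cells held 1023 genes, and the cause was not tested. With each array's own floor 19006 genes passed between synergid cells and soaked ovary and 2538 were synergid-enriched, where dim spots of the brighter arrays are no longer raised to the synergid floor. With a fold minimum of 2, 7557 genes passed between egg and synergid cells, and without one the sets held 3883, 2243 and 2789 genes, by construction. Of 83 genes named, each counted per comparison, 51 can be tested among probes detected on all arrays of both groups, since the others are not detected on all 3 arrays of the dimmer group. Under the other settings that refit all comparisons 81 to 83 stayed past the threshold. Of the rest the S6 kinase gene Os03g0334000 lost its call with 1 fit of 15 arrays and with a single floor over 15 arrays, and the others had no value. Settings with a replicate left out or egg replicate 3 alone refit 24 to 40 of the 83, which all stayed past it. A value of exactly 0, with both groups at the floor, counts as no longer past the threshold.

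With camera and an estimated correlation 0 of the 99 list calls held (18 of 168 lists had an unadjusted p under 0.05), while fry, which asks only whether a list moves on balance one way, passed 131 lists. Fry took the opposite direction for seed storage proteins between egg and synergid cells (median 0.11, adjusted p = 0.00806) and, between synergid cells and whole plants, for cell wall (0.07, 0.0319), jasmonate (0.21, 0.0225) and AP2/ERF genes (-0.06, 0.00482), lists with medians near 0 that it does not compare with other genes. After normexp the direction reversed for the secretory pathway (-0.03, 0.0395) and core histones (-0.17, 0.0333) between egg and synergid cells. Translation factors between synergid cells and soaked ovary (0.70, 0.532) and F-box and SKP1 proteins between untreated ovary and whole plants (-0.64, 0.921) lost their call after normexp. The test took the opposite direction for both but did not pass. The cause of these changes was not tested. Over 1008 list values under other settings, 822 kept their call or stayed without one, 125 lost the call, 53 gained one and 8 reversed. Direction was not compared where neither setting called the list. Those counted as reversed include calls lost with the opposite sign.

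Leaving out each replicate gave 10713 to 12081 genes for egg against synergid cells, 10540 to 16491 for soaked against untreated ovary, 13551 to 17232 and 11284 to 14131 for egg and synergid cells against soaked ovary, 12372 to 16433 and 10130 to 13887 against whole plants, and 8300 to 15511 for untreated ovary against whole plants. The sets held 2187 to 2296 egg-enriched, 1273 to 1494 synergid-enriched and 1614 to 1677 genes of both cells. With a replicate block, paired by number, the 7 comparisons in the order of the report gave 11750, 13825, 14708, 12302, 13587, 10905, 11790 genes and the sets 2242, 1430 and 1664, and 99 list calls. That block ended the call of F-box and SKP1 proteins between synergid cells and soaked ovary (adjusted p = 0.0556) and made one of AP2/ERF genes between untreated ovary and whole plants (0.0388), and changed no other call. A slide block, which between egg and synergid cells leaves egg array 3 as the only egg sample, gave 11052, 13825, 14849, 11919, 14147, 10974, 11790 genes in the same order and sets of 2249, 1143 and 1652. With egg replicate 3 alone, assumed to vary like the other groups, egg comparisons gave 9602, 12307 and 9615 genes.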

Other observations

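Every test in this part was written down before its result was seen. The 3 remaining pairs of groups serve the enriched sets and belong to no comparison of the report. Egg cells and untreated ovary differed in 15319 of 23728 genes, 8627 higher in the egg cell, and synergid cells and untreated ovary in 13289 of 19468, 7099 higher in the synergid cell. Soaked ovary and whole plant differed in 10544 of 25153, 4910 higher in the ovary. The 10 brightest genes took 14.6 to 17% of all signal on synergid arrays, 5.08 to 7.92% on egg, 4.13 to 5.75% on soaked ovary, 3.52 to 4.2% on untreated ovary and 7.41 to 8.63% on whole plant arrays.

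Egg-enriched genes were mostly lower in the soaked ovary, 60.33% against 29.65% of all genes. Among 2798 genes picked on egg, synergid and whole plant arrays alone, 57.18% were lower, which argues against use of the same ovary arrays for the set and the test. The smallest excess over all genes under other scalings was 21.07 points, after normexp (39.65% against 18.58%). An excess thus remained under each scaling, but a smaller share was lower after normexp, so scaling may account for part of it. Quantile normalization and the percentile over detected probes moved the median of all genes by only -0.048 and -0.046, so they test scaling little. Medians within slides 3, 4 and 5 were -0.91, -1.13 and -1.11, against 0 for all genes on each, which argues against slides. A hypothesis left by these tests is that genes with high RNA in egg cells, ribosomal proteins among them, may also be ones whose RNA falls in tissue kept in mannitol. The data do not show whether the isolated cells changed in the same way, and time out of the plant and mannitol cannot be separated if only the soaked ovaries were kept for 8 h.

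Egg and synergid cells differed in 11833 of 19669 genes, 60.2%. Genes called from egg arrays of slide 1 against 2 synergid arrays kept their sign between egg array 3 and the synergid array left out, on slide 2, in at least 92.42% of cases (92.42, 95.73, 94.28%), which argues against slides as the cause of the calls. Of 6297 genes at least 4 times the floor on all 6 arrays 69.32% passed, so the calls were not confined to genes under that level. With a 75th percentile signal of 46.2 to 70 on the synergid arrays, such genes can still be dim there. The filter therefore cannot decide about dim synergid signal. A difference between the 2 cell types remains a likely explanation and was not tested apart from dim signal, handling or the number of cells pooled. Amplification of unequal RNA amounts would act on whole arrays of a group and was not tested.

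The largest folds favoured the synergid cell, with 213 genes at least 16-fold higher there and 81 at least 16-fold higher in the egg cell. Among 11439 genes above the floor on all 6 arrays the numbers were 72 and 47, but that filter takes out the largest folds either way and the floor is the same on all 6 arrays, so the test decides nothing about the floor. After quantile normalization the numbers were 318 and 242, a smaller ratio that leaves open whether scaling accounts for part of the excess. A few bright transcripts of the synergid cell, which take a larger share of its signal, stay open as an untested biological explanation.

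The 6 arrays of a comparison can be split into groups of 3 in 10 ways, too few for a share under 0.05. In each of the 7 comparisons 1 of the 10 splits, the real one, gave as many genes as reported (11833, 13427, 14987, 12557, 14334, 11687, 11797), and the highest of the others gave 0 (in limma, at most 782 at an unadjusted p under 0.05). For the paired tissues that holds among the other splits that part 3 pairs, as the real one does, and among those that part 1. Every other split mixes arrays of unlike groups, which widens the spread within each. Gene counts near 0 were thus to be expected there and do not exclude chance. Lists called by camera in the real split, in the highest other split, and the number of splits with as many were 16, 11 and 1 for egg against synergid cells, 11, 9 and 1 for soaked against untreated ovary, 18, 15 and 1 and 14, 15 and 2 for egg and synergid cells against soaked ovary, 16, 17 and 5 and 12, 14 and 4 against whole plants, and 12, 10 and 1 for untreated ovary against whole plants. In 3 comparisons another split thus called more lists than the real one. Every other split keeps part of the real difference between groups, so the splits cannot say how many lists would be called without any change.

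Of 100 groupings of the 15 arrays 1, the real one, gave as many genes as each set held (2237, 1403 and 1668), the highest of the others giving 0. Since the groupings mix unlike groups, which widens the spread within each, and a set needs several 2-fold calls per gene, values near 0 were to be expected, so this count excludes neither chance nor an effect of slides. Part of the excess of genes shared by both cells, 1668 against 814 if independent, may come from the tissue arrays that serve both cells, which are too few to split between them.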
